A study of Arabidopsis thaliana with 3 samples.

How the data were processed

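Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was made with Arabidopsis thaliana Col-0 seedlings that carry JMJ28, a JmjC-domain histone demethylase, with a FLAG epitope tag under its own promoter. Per the labels, plants grew in long days at 22 °C and were taken at 14 days, with 2 ChIP libraries from separate biological replicates and 1 input library. Per the submitters' processing notes, reads were handled with Bowtie2 (an aligner) and MACS2 (a peak caller) on the TAIR10 build. Versions, the peak threshold, whether the ChIP libraries were pooled and how the input was used are not given in the sources used here.

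The deposited file is a single list of 18410 peak summits, each an interval of 1 bp with a name and a score. The score in the authors' file is in the layout of a MACS2 summit list, where it is the −log10 of a q-value or p-value for that summit. It is a strength of evidence that grows with sequencing depth, and it is neither a coverage nor an occupancy level. Only 790 distinct scores occurred. With this single list, no value per library, no sequencing depth and no spread between replicates was analysed here. Every p-value below therefore compares this list with random placement or with other genes, and none measures variation between plants.

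Genes came from an NCBI table of the TAIR10.1 assembly with names, types and extents of 37887 nuclear genes, 27432 of them protein-coding. It was used to decide which summits lie in or near which genes, and only the summit positions of the file are printed (counted from 1, TAIR10). To check that both share coordinates, the share of summits within 300 bp of a gene end was computed in 26 bins of 5 Mb after shifting the summits in steps of 200 bp. In 26 of 26 bins the highest share was at no shift. The lowest share without a shift was 47.7%, and the highest after a shift of 5000 bp was 29.2%.

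The table gives neither strand nor exons, and no genome sequence or transposon annotation was used here. The plan written before the data were examined was adapted accordingly. Distances were taken to the nearest end of a protein-coding gene, which can be its transcription start or its transcript end. A gene was counted as having a summit when one lay within it or within 1000 bp of either end. Summits were sorted into 4 classes: inside a protein-coding gene, outside but within 1000 bp of one, inside another annotated gene only, and elsewhere. Motifs, base composition, transposon overlap, and exon, intron or promoter classes were not analysed here, nor were peak widths or covered length.

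Summits were set against 1000 random placements on the same chromosomes, between the first and the last annotated gene, with a two-sided placement p whose smallest possible value is 0.001. Windows of 500 kb with a protein-coding gene density under 50% of their chromosome's median were called gene-poor, from the annotation alone. Scores near to and far from gene ends were compared with a two-sided permutation test of medians with 100000 resamples (smallest possible p 1e-05). Each of 14 gene lists, written from textbook knowledge before the data were examined, was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 14 lists and a threshold of 0.05. The lists hold 278 genes, and 262 of the 280 entries had the listed symbol as symbol or synonym in the table. The other entries were matched by locus identifier. Intervals of shares are exact 95% binomial intervals and cover counting error only. Random lists matched on gene length (10000 per list, deciles of length) served as an alternative.

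Genes were named by a rule also set before the data were examined. It takes the genes nearest to the 10 highest scores, and every member with a summit of the lists for photoperiodic flowering, circadian clock, other flowering regulators and histone demethylases, with values for up to 6 of each. It adds up to 4 members with the highest scores of every other list, and CO, FT and JMJ28 in any case. Gene families by symbol (11) and gene types were added after the data had been seen, as were circular shifts, counting inside the gene only, flanks of 2000 bp for gene counts, and counting each summit for its nearest gene only. Ribosomal protein symbols that belong to disease resistance genes were left out of that family.

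Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The tests were checked on simulated data. With random summits, 3.33% of 120 placement tests fell under 0.05. Simulated lists of 25 genes with an odds ratio of 3 fell under an unadjusted p of 0.05 in 47.5% of 200 runs, and with an odds ratio of 10 in 95.0%. For lists of 15 genes these shares were 37.0% and 84.5%, so moderate differences of short lists can be missed. The random summits were spread evenly and set against fewer placements than the real ones. All genes outside a simulated list had the same independent chance of a summit. In the data this chance varied with gene length and neighbouring genes could share a summit, which the simulations did not cover.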

Results

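The data were a genome-wide list of sites recovered with FLAG-tagged JMJ28 from 14-day-old Arabidopsis seedlings grown in long days. JMJ28 is a JmjC-domain protein of the family that removes methyl groups from lysine 9 of histone H3, and the experiment asked where in the genome it is found. No library without the tag was used here, so chromatin recovered without JMJ28 cannot be told apart from sites of JMJ28. There were 2 ChIP libraries and 1 input library, and the values came from 1 list of 18410 peak summits made by the authors. Of these, 18368 lay on the 5 nuclear chromosomes and 42 on the chloroplast genome, and none on the mitochondrial genome. The nuclear summits had a median score of 9.07 (interquartile range 5.10 to 18.4), where the score is the authors' own −log10 value for each summit. Chromosome 5 had the most summits per 100 protein-coding genes (70.8) and chromosome 2 the fewest (59.2).

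Summits of JMJ28 lay in the gene-rich chromosome arms and were scarce around the centromeres. The 37 gene-poor windows among 240 windows of 500 kb held 276 summits, or 1.50% of the nuclear summits. Random placement put 15.5% ± 0.269 (SD, 1000 placements) there, 10.3 times as many (placement permutation p = 0.001, the smallest that 1000 placements can give). The scarcity exceeded the low number of genes in these windows: 22.6% of their 1013 protein-coding genes had a summit, against 67.1% of the genes elsewhere. Whether reads could be placed uniquely in these windows was not examined, and random placement made no allowance for it. A lack of callable sequence there therefore cannot be told apart from a lack of JMJ28.

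**Figure D1:**
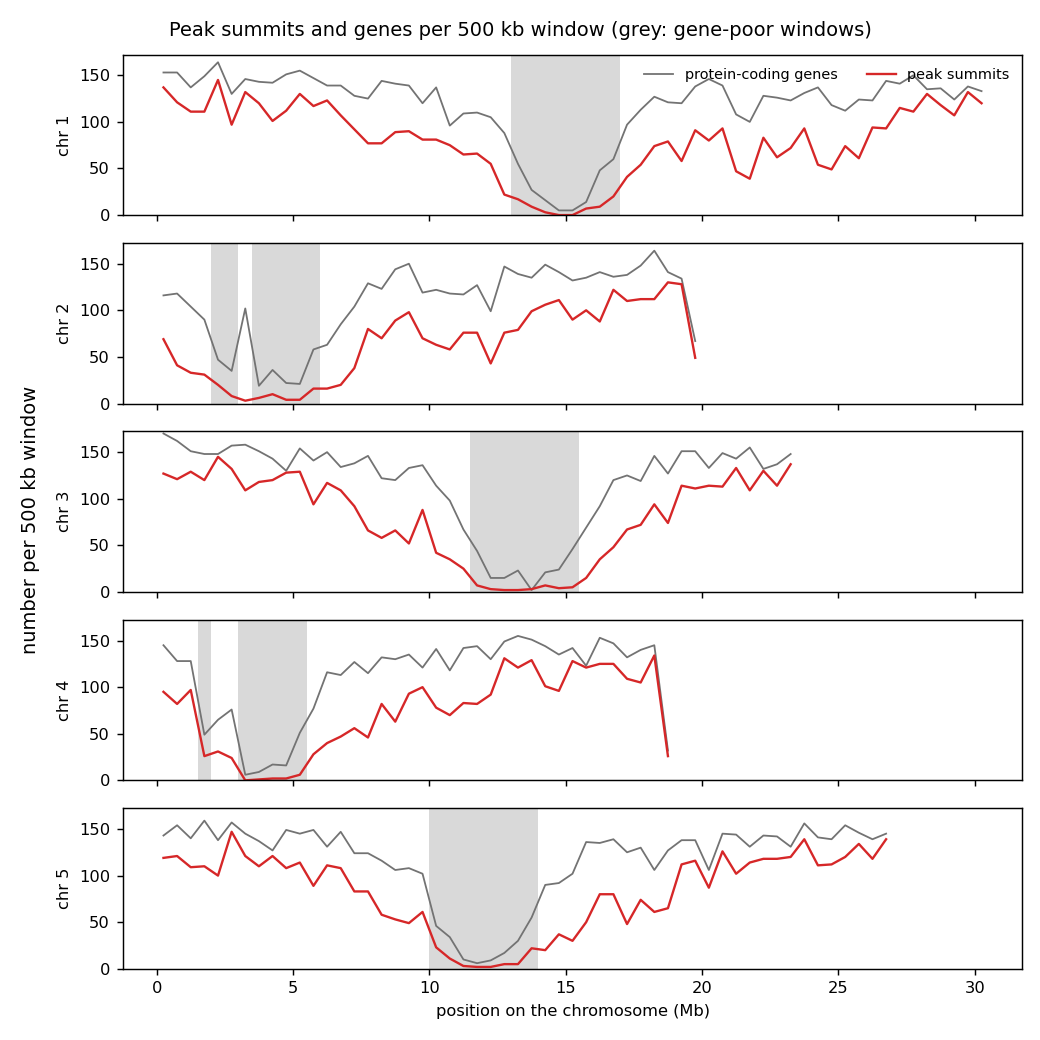
Number of peak summits (red) and of protein-coding genes (dark grey) per 500 kb window along each of the 5 nuclear chromosomes, with position in Mb on the horizontal axis and gene-poor windows shaded. The 37 shaded windows held 276 of the 18368 nuclear summits.

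Within the arms, the summits were on genes. Of the nuclear summits, 16196 (88.2%) fell inside a protein-coding gene, against 54.3% ± 0.381 (SD) with random placement. Another 1803 (9.82%) lay outside but within 1000 bp of one, where random placement gave 20.4%. Pseudogenes, RNA genes and other annotated genes alone held 171 summits (0.931%, against 8.55%), and 198 summits (1.08%, against 16.8%) lay elsewhere. All 4 classes differed from random placement with an adjusted placement permutation p of 0.001, the smallest possible. Placed at random within gene-rich windows only, 62.2% of summits fell inside protein-coding genes, still below the 88.4% observed there.

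JMJ28 summits gathered just inside the ends of genes. Within 500 bp of a protein-coding gene end lay 13798 summits (75.1%), against 35.4% ± 0.359 (SD) with random placement (permutation p = 0.001, the smallest possible). The fullest 100 bp interval was 100 to 200 bp inside a gene end, with 3298 summits against a random mean of 849, a ratio of 3.88. Summits inside genes lay a median of 284 bp from the nearer end (interquartile range 160 to 487 bp). Summits within 500 bp of a gene end also had higher scores, with a median of 9.67 against 7.11 for the other 4570. This difference of 2.56 passed a two-sided permutation test (p = 1e-05, the smallest that 100000 resamples can give). Strand was not used here, so transcription starts and transcript ends were counted together.

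**Figure D2:**
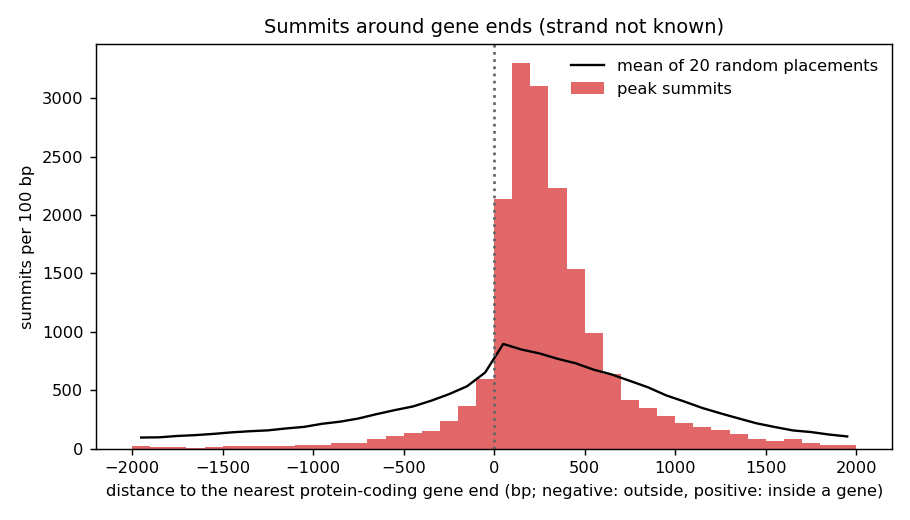
Number of peak summits per 100 bp (bars) by distance to the nearest protein-coding gene end in bp, with negative distances outside and positive distances inside a gene, and the mean of 20 random placements (line). The fullest interval, 100 to 200 bp inside a gene end, held 3298 summits.

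Counted with flanks of 1000 bp, most protein-coding genes had a summit. Of 27432 protein-coding genes, 17946 (65.4%) had a summit within them or within 1000 bp, against 13102 ± 72.3 (SD) with random placement and 12758 ± 508 (SD) with circular shifts that keep the spacing of the summits (random placement permutation p = 0.001, the smallest possible). A single summit was found at 9771 genes, 2 summits at 6433, and 3 or more at 1742. Longer genes had a summit more often: the share went from 33.4% in the shortest length decile of genes, with a median length of 528 bp, to 83.0% in the longest. With summits inside the gene only, 13097 genes (47.7%) were counted, and 13851 when each summit counted for its nearest gene only.

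The highest scores belonged to HDA6, a histone deacetylase of the RPD3 type. Its summits at positions 25317950 and 25317034 of chromosome 5, both inside the gene, scored 5357 and 4897. A further summit inside HDA6 scored 34.9, and the 3 summits within 10 kb outside it, all at higher positions, scored 3.00, 5.34 and 19.2. JMJ28 itself (AT4G21430) had 1 summit, inside the gene at position 11412230 of chromosome 4, with a score of 1443, the next highest of the nuclear genome. FLC, the MADS-box repressor of flowering, was also among the 10 highest, with a summit inside the gene at position 3178918 of chromosome 5 (score 762) and a weaker one of 45.3. The summits within 10 kb outside FLC scored only 3.78 and 15.7. Whether extra DNA of the gene in the libraries raised the FLC score was not tested. The other nuclear summits among the 10 highest lay inside AT1G58230 (chromosome 1, position 21566129, score 1182), within 1000 bp of AT3G21080 (chromosome 3, position 7388056, score 935) and inside AT3G60660 (chromosome 3, position 22421443, score 719). The remaining 3 of the 10 were on the chloroplast genome, at positions 102323 (1743), 136340 (1724) and 55851 (719). Scores above 200 were rare in the nucleus, at 59 summits or 0.321%. The tagged transgene carries JMJ28 sequence of its own, and no library without the tag was used here.

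**Figure D3:**
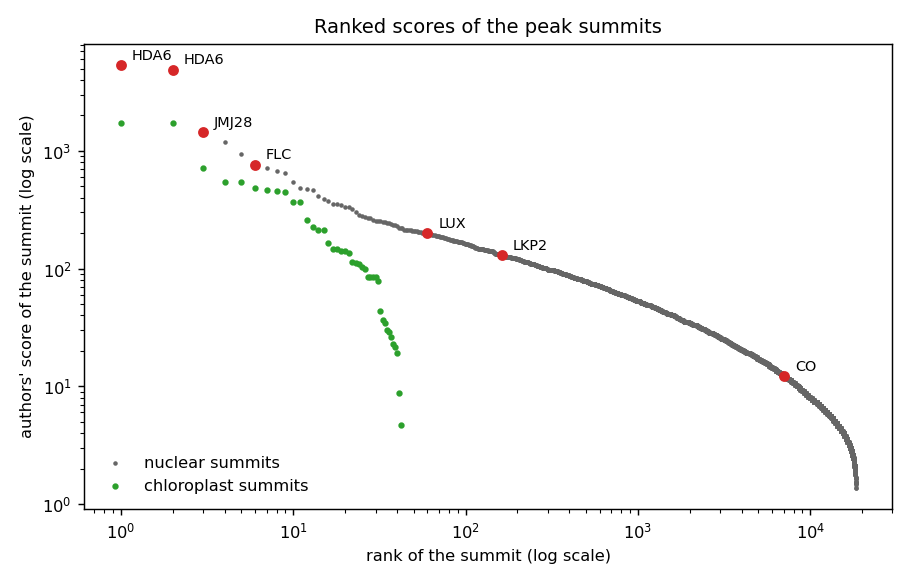
The authors' score of each summit against its rank, both on log axes, for nuclear (grey) and chloroplast (green) summits ranked separately. Red points mark HDA6, JMJ28, FLC, LUX, LKP2 and CO, whose highest scores were 5357, 1443, 762, 199.7, 129.9 and 12.2, and the 2 HDA6 points stand apart from the rest. The LKP2 summit lay outside the gene.

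The gene lists asked which parts of seedling biology carried JMJ28 summits more or less often than other genes. Among 14 lists, 3 had more genes with a summit than the rest of the genome, 3 had fewer, and 8 did not pass the test. Light signalling and circadian clock genes all had a summit. So did nearly all members of the stress-response transcription factor list, which also holds the jasmonate repressor genes JAZ1, JAZ5 and JAZ10. Auxin genes, regulators of meristem, floral and embryo identity, and seed storage genes mostly lacked one. The score given for a gene is the highest among summits inside it or within 1000 bp, so it can belong to a neighbouring gene. The scored summit lay outside the gene at TOC1, CCA1, CHE, RVE8, FHY1, WRKY33, JAZ5, CUC1, CLV1 and PI. The same held for SESA1, OLEO1, TIR1, ARF19, LKP2, FBH4, CDF1, SMZ, FRI, JMJ32 and CMT2. It also held for EF1A-A4, ACT2, EF1A-A1, LHCA1, LHCA3 and LHCB3.

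Circadian clock genes had a summit in 20 of 20 cases (100%, exact 95% interval 83.2 to 100), against 65.4% of other genes (Fisher's exact test, adjusted p = 0.00173). LUX, a component of the evening complex, had the highest score of the list (199.7, chromosome 3, position 17185012). It was followed by TOC1 (60.8) and CCA1 (59.0), core repressors of the clock, then CHE (53.8), PRR5 (41.0) and RVE8 (40.5). The other members with a summit were LHY, PRR3, PRR7, PRR9, ELF3, ELF4, BOA, RVE1, RVE4, RVE6, LNK1, LNK2, GI and ZTL. The call rested partly on summits in the flanks: with summits inside the gene only, the share was 70.0% against 47.7% and the adjusted exact p 0.110. It was also lost with the upper 50% of scores (65.0% against 43.0%, adjusted exact p = 0.239) and when each summit counted for its nearest gene only (70.0% against 50.5%, adjusted exact p = 0.180).

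Light signalling genes had a summit in 22 of 22 cases (100%, interval 84.6 to 100, adjusted exact p = 0.00173), a call against other genes that held in each alternative tried. The highest scores were at PIF3 (92.6), PIF7 (74.6) and PIF4 (54.3), phytochrome-interacting bHLH factors, and at FHY1 (79.1), which carries phytochrome A into the nucleus. Of the stress-response transcription factor list, 17 of 18 genes had a summit (94.4%, interval 72.7 to 99.9, adjusted exact p = 0.0248). Among them were WRKY33 (157), a regulator of defence, ZAT10 (70.1), a zinc finger protein induced by abiotic stress, and the jasmonate repressors JAZ1 (68.9) and JAZ5 (57.9). JAZ10 was the member without a summit. The stress list did not pass with the upper 50% of scores (61.1% against 43.0%, adjusted exact p = 0.307) or with the nearest gene only (77.8% against 50.5%, adjusted exact p = 0.0987). Constitutively transcribed reference genes also had a high share (13 of 14, 92.9%), and neither the light signalling nor the stress list was compared with them.

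Regulators of meristem, floral and embryo identity had a summit in 7 of 22 cases (31.8%, interval 13.9 to 54.9, adjusted exact p = 0.00861). The highest scores were at CUC1 (16.9), which sets organ boundaries, the meristem receptor CLV1 (9.67), the floral organ gene PI (6.58) and SHP1 (4.42). WUS, STM, AG, LEC1, LEC2 and FUS3 were among the 15 without a summit, which were listed here after their values were seen. The list no longer passed with the nearest gene only (adjusted exact p = 0.158), where its share stayed at 31.8% and that of other genes was 50.5%. Of the 11 seed storage and oil body genes, 2 had a summit (18.2%, interval 2.28 to 51.8, adjusted exact p = 0.00861). These were the albumin gene SESA1 (68.9) and the oleosin gene OLEO1 (16.5), both with the summit outside the gene. The seed list did not pass against random lists of the same gene lengths (50.1%, adjusted permutation p = 0.0695) or with the upper 50% of scores (adjusted exact p = 0.307).

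Auxin genes had a summit in 10 of 25 cases (40.0%, interval 21.1 to 61.3, adjusted exact p = 0.0248). The receptor gene TIR1 (91.2), the response factor genes ARF6 (54.3) and ARF19 (50.9) and the repressor gene IAA3 (41.0) had the highest scores. The list was uneven, as seen after its values were known: 5 of 5 ARF genes had a summit, against 2 of 11 Aux/IAA repressor genes and 0 of 4 YUC genes of auxin synthesis, a split that was not tested. The call was lost with the upper 50% of scores (24.0% against 43.0%, adjusted exact p = 0.239), inside the gene only (32.0% against 47.8%, adjusted exact p = 0.203), with the nearest gene only (36.0% against 50.5%, adjusted exact p = 0.231) and with flanks of 2000 bp (52.0% against 73.3%, adjusted exact p = 0.0523).

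**Figure D4:**
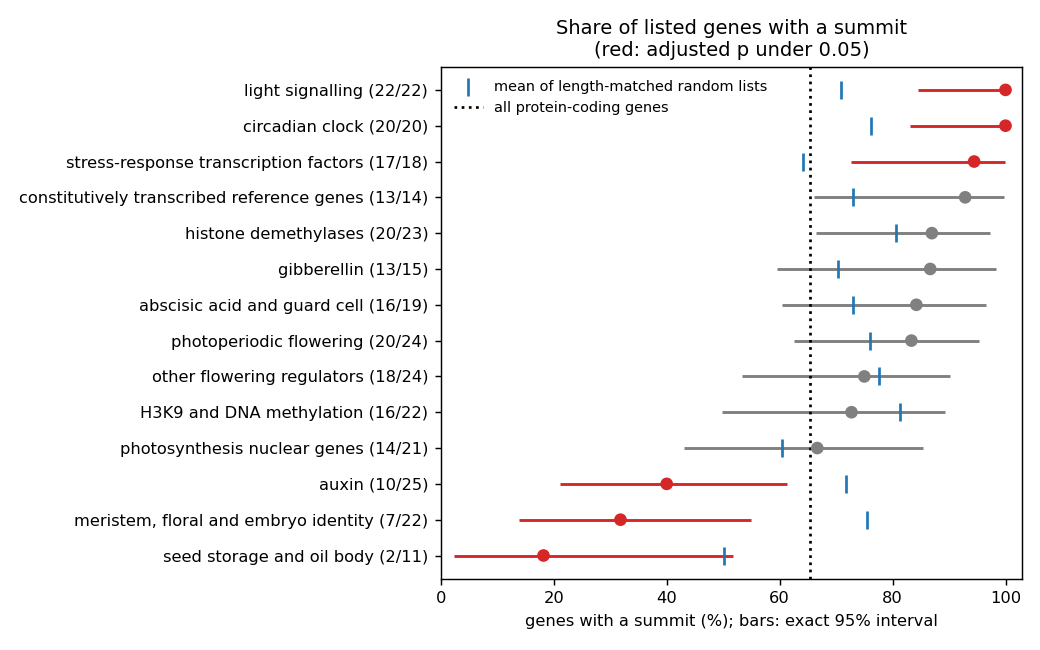
Share of genes with a summit in each of 14 gene lists (points, percent) with exact 95% intervals (bars), the mean of length-matched random lists (blue ticks) and the share of all protein-coding genes (dotted line, 65.4%). Red marks the 6 lists that passed the adjusted exact test, from light signalling (22 of 22) to seed storage and oil body (2 of 11).

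Flowering time genes were of interest because JMJ28 was studied for photoperiodic flowering. CO, the central activator of flowering in long days, had 1 summit, inside the gene at position 5170593 of chromosome 5, with a score of 12.2. This score was equal to or above that of 61.9% of nuclear summits. FT, which encodes the mobile flowering signal, had none within it or within 10 kb. Of the photoperiodic flowering list, 20 of 24 genes had a summit (83.3%, interval 62.6 to 95.3), which did not pass the test (adjusted exact p = 0.131). The blue-light F-box gene LKP2 had the highest score (129.9, chromosome 2, position 8194222), followed by FBH4 (51.5), which encodes a bHLH activator of CO. Next came the CO relative COL2 (48.6), the CO repressor gene CDF1 (36.4), COL1 (34.4), which neighbours CO, and FKF1 (31.5). The summits of LKP2, FBH4 and CDF1 lay outside the gene. GI, ZTL, CDF2, CDF3, CDF5, FBH1, FBH3, COP1, PHYA, CRY1, CRY2, PHYB and COL5 also had a summit, while TSF, FBH2 and SPA1 had none.

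Other flowering regulators had a summit in 18 of 24 cases (75.0%, interval 53.3 to 90.2, adjusted exact p = 0.460). Their share was below that of random lists of the same gene lengths (77.6%, adjusted permutation p = 0.801) and, with the upper 50% of scores, below that of other genes (29.2% against 43.0%, adjusted exact p = 0.337). After FLC, the highest scores were at SMZ (78.5), an AP2-type repressor, FLD (36.4) and FVE (32.4), both autonomous-pathway genes, FRI (11.6) and TEM2 (11.6). SOC1, LFY, FD, FCA, LD, FY, TEM1, TOE1, TOE2, MAF2, MAF3 and MAF4 also had one, with MAF2 and MAF3 sharing a summit. The difference between the photoperiodic list and this list did not pass Fisher's exact test (adjusted p = 0.724 over 5 pairs of lists chosen after the data were seen).

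Histone demethylase genes had a summit in 20 of 23 cases (87.0%, interval 66.4 to 97.2, adjusted exact p = 0.0576), just short of the threshold. After JMJ28, the highest scores were at JMJ32 (57.3), JMJ20 (42.6), JMJ24 (41.6), the H3K27 demethylase gene REF6 (34.4) and JMJ22 (27.3). ELF6, JMJ13, JMJ14, JMJ16, JMJ18, JMJ21, IBM1, JMJ26, JMJ27, JMJ29, JMJ30, JMJ31, LDL1 and LDL2 also had one. JMJ15, JMJ17 and LDL3 had none. With summits inside the gene only, this list passed (78.3% against 47.7%, adjusted exact p = 0.0150), as it did with the nearest gene only (adjusted exact p = 0.0498). Without JMJ28 itself the adjusted exact p was 0.0245 and 0.0792. The nearest-gene share was then 77.3% against 50.5%, close to the 78.3% with JMJ28, so that call was borderline. It did not pass against random lists of the same gene lengths (80.6%, adjusted permutation p = 0.700), with the upper 50% of scores (adjusted exact p = 0.337) or with flanks of 2000 bp (adjusted exact p = 0.209). Genes of H3K9 and DNA methylation had a summit in 16 of 22 cases (72.7%, adjusted exact p = 0.705), a share below that of random lists of the same gene lengths (81.4%, adjusted permutation p = 0.575). They were led by the silencing gene MOM1 (129.9), the DNA methyltransferase genes CMT2 (73.3) and MET1 (67.0), and NRPE1 (53.2), the largest subunit of RNA polymerase V.

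The remaining lists did not pass the test. Abscisic acid and guard cell genes had a summit in 16 of 19 cases (84.2%, adjusted exact p = 0.133), with NCED3 (57.3), an enzyme of abscisic acid synthesis, the kinase OST1 (53.8), ABF3 (45.9) and ABF1 (20.4) highest. Gibberellin genes had one in 13 of 15 cases (86.7%, adjusted exact p = 0.133), with the receptors GID1A (43.7) and GID1C (15.7) and the DELLA repressors RGL3 (29.1) and RGL1 (14.3) highest. They passed with summits inside the gene only (80.0% against 47.7%, adjusted exact p = 0.0404). They did not pass against random lists of the same gene lengths (70.3%, adjusted permutation p = 0.447), and with the upper 50% of scores their share was below that of other genes (40.0% against 43.0%, adjusted exact p = 1). Constitutively transcribed reference genes had one in 13 of 14 cases (92.9%, adjusted exact p = 0.0778), among them EF1A-A4 (59.0), UBQ10 (44.8), ACT2 (18.0) and EF1A-A1 (15.4). Nuclear photosynthesis genes had one in 14 of 21 cases (66.7%, adjusted exact p = 1), with the antenna genes LHCA1 (46.4), LHCA3 (44.2) and LHCB3 (26.8) and the photosystem I gene PSAD1 (33.9) highest. The 7 without a summit were copies of the LHCB1, LHCB2 and RBCS genes, whose near-identical sequences can share reads, so their state is uncertain.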

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

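All tests in this part were chosen after the result had been seen. The chloroplast genome held 42 summits, which entered no comparison above, and with no other chloroplast measurement at hand this is simply a signal outside the nuclear analysis. Their median score was 125, or 13.8 times the nuclear median, and 15 of them exceeded 200. A nuclear protein is not expected on plastid DNA, and seedlings contain many plastid genomes per cell. A candidate explanation is that plastid DNA in excess was scored against one background level for the whole genome. Scores would then depend on read number alone and repeat often, and 94.5% of nuclear summits did share their score with at least 10 others. That value concerns the nuclear background and does not measure plastid DNA, so the explanation stays open. How the input entered peak calling is not given in the sources used here, and no biological explanation was tested.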

How the results depend on the processing

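The upper 50% of scores, length-matched lists, 100 kb windows, gene-rich placement and other flanks of the position classes were planned; circular shifts, inside-only counting, 2000 bp flanks for genes, nearest-gene counting, leaving out shared members or JMJ28, and the family settings were chosen after seeing the data. The position classes, the share near gene ends, the share in gene-poor windows and the score difference kept their direction and stayed past their tests in each alternative run; the score difference was 3.04 at 1000 bp. With the upper 50% of scores, 9022 summits and 11804 genes remained by construction, and adjusted p was 0.239 for clock and for auxin, and 0.307 for stress and for seed genes. Inside the gene only, it was 0.110 for clock, 0.203 for auxin, 0.0150 for histone demethylases (0.0245 without JMJ28) and 0.0404 for gibberellin. With the nearest gene only, it was 0.180 (clock), 0.231 (auxin), 0.0987 (stress), 0.158 (meristem) and 0.0498 (histone demethylases; 0.0792 without JMJ28). Auxin reached 0.0523 with 2000 bp flanks, and seed genes 0.0695 with matched lengths. The SAUR family turned from lower to slightly above its length-matched lists (43.8% against 42.3%, adjusted permutation p = 0.865), since its genes are short. Core histones passed with matched lengths (adjusted permutation p = 0.0140). The causes of these changes were not tested. All 6 called lists kept their direction inside the gene only, with the nearest gene only and with the upper 50% of scores. The midpoint and 1 bp overlap alternatives equal the summit by construction; promoter-only counting and the motif, base composition and transposon alternatives were not run. No paired analysis was possible because a single list held no values per library. Depth is unknown, so summits missed for lack of reads cannot be counted.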

Other observations

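The tests of the lists against other genes and against length-matched lists were planned. The nearest-gene test was set before its own result was seen, and all other tests in this part were chosen after the data had been seen. Gene types other than protein-coding differed widely. Only 5.77% of 3917 genes typed as pseudogene had a summit within them or within 1000 bp, against 47.1% with random placement. Of these genes, 1272 lay in gene-rich windows, where the shortfall held (14.6% against 51.4%, adjusted placement permutation p = 0.001, the smallest possible). The shortfall was smaller for 926 genes typed as transcribed pseudogene (27.0% against 37.0%, and 33.1% against 41.0% in gene-rich windows, both with an adjusted permutation p of 0.001). No transposon annotation was used, so whether the pseudogene type holds transposon genes was not examined. Whether reads could be placed uniquely at pseudogenes was not examined. Small nucleolar RNA genes, which guide ribosomal RNA modification, had one in 73.9% of 287 cases against 27.7%. Transfer RNA genes (55.4% of 625, against 27.5%), spliceosomal snRNA genes (56.1% of 82, against 29.3%) and antisense RNA genes (64.6% of 79, against 30.6%) were likewise higher, each with an adjusted permutation p of 0.001. A summit inside the gene was found at 4.88% of snoRNA, 4.64% of transfer RNA, 12.7% of antisense RNA and 18.3% of snRNA genes. Their summits thus often lay in a neighbouring gene or a flank, and no random share was computed for summits inside. MicroRNA genes did not pass the test against random placement (29.8% against 28.5%, adjusted permutation p = 0.713).

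Families named by gene symbol also differed from other genes by Fisher's exact test, adjusted over 11 families. Ribosomal protein genes found by symbol had a summit in 46 of 51 cases (90.2%, adjusted exact p = 0.000186), led by RPL24 (score 252) and RPL15 (109). They were not split into cytosolic and organellar ribosomal proteins, and genes without such a symbol were not counted. Defensin-like peptide genes had one in only 13 of 86 (15.1%, adjusted exact p = 7.88e-21), MYB genes in 47 of 125 (37.6%, adjusted exact p = 1.05e-09) and cytochrome P450 genes in 104 of 234 (44.4%, adjusted exact p = 3.75e-10). Random lists of the same gene lengths had 37.7%, 65.1% and 71.6%, so part of the defensin gap went with short genes, and all 3 families stayed below them (adjusted permutation p = 0.000275). WRKY genes (33 of 71, adjusted exact p = 0.00198), NAC genes (51 of 100, adjusted exact p = 0.00481) and numbered bHLH genes (9 of 22, adjusted exact p = 0.0315) were lower as well. With summits inside the gene only, the WRKY (39.4% against 47.8%, adjusted exact p = 0.210) and bHLH calls (27.3% against 47.8%, adjusted exact p = 0.0704) were lost. Some members of the lower families nevertheless scored high, such as NAC062 (677) and WRKY46 (284). The ERF family (17 of 25, adjusted exact p = 1), heat shock proteins and factors (36 of 50, adjusted exact p = 0.411) and core histones (16 of 20, adjusted exact p = 0.293) did not pass. Core histones did pass against random lists of the same gene lengths (80.0% against 50.4%, adjusted permutation p = 0.0140). The most summits at 1 gene were 6, at BGAL1 and SLOMO. On chromosome 2, the 500 kb window centred at 3.25 Mb, where Col-0 carries a large insertion of mitochondrial DNA, had 102 protein-coding genes and only 3 summits. Whether reads could be placed uniquely in that window was not examined either.

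HDA6 stood out, with a highest score 3.71 times that of JMJ28, the next nuclear gene. A gain of a chromosome segment would raise the neighbours too. Towards higher positions this is argued against, since the 3 summits within 10 kb had a median score of 5.34, below the nuclear median of 9.07. Towards lower positions no summit lay within 10 kb, and the 3 nearest had a median of 42.6, between the nuclear upper quartile of 18.4 and the 95th percentile of 55.8, which leaves a gain on that side open. Extra DNA of the gene itself, such as a construct or amplified DNA, may account for the scores. The highest score within 10 kb outside the gene, 19.2, leaves this open because strong binding to HDA6 would also end at the gene. Beyond 10 kb, the 3 nearest summits at lower positions scored higher, at 69.5, 20.8 and 42.6. The open explanations cannot be told apart without reads or an untagged control. The score of 1443 at JMJ28 has the same open point, since the transgene adds copies of that gene. By its title, the input library comes from the same tagged line and would carry the same genomic copies. How the input entered peak calling is not given, so it cannot decide between these explanations.

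The lists with more or fewer summits may reflect gene length, neighbouring genes or transcription. That longer genes offer more room for a summit is argued against as the whole cause, since 5 of the 6 called lists also passed against length-matched random lists in the same direction. Summits of neighbouring genes counted in the 1000 bp flanks remain an open explanation, because 2 counts of the same lists came out differently. When each summit counted for its nearest gene only, 2 of 6 lists passed (light signalling and seed), which met the sign of this cause set beforehand, under 50% of the lists. The lost calls kept a gap, though: stress genes had 77.8% (adjusted exact p = 0.0987) and clock genes 70.0% (0.180), against 50.5% of other genes, and meristem genes had 31.8% (0.158) and auxin genes 36.0% (0.231). With summits inside the gene only, a count looked at afterwards, 4 of 6 passed, and clock (0.110) and auxin genes (0.203) did not. In both counts 6 of 6 lists kept their direction.

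Transcription in seedlings is a candidate explanation that the lists leave open. Photosynthesis genes, abundantly transcribed in green tissue, did not pass the test against other genes (66.7% against 65.4%), nor did their difference from reference genes (exact p = 0.108, adjusted p = 0.180 over 5 pairs of lists). Reference genes had a summit more often than seed storage genes, which are silent in seedlings (92.9% against 18.2%, adjusted exact p = 0.000597), as transcription would give, although seed genes are short and did not pass against lists of their lengths. The clock list (20 of 20) did not pass against reference genes (13 of 14, adjusted exact p = 0.515). With every clock gene already counted, this test could not have shown a higher share in the clock list. Of the LHCB1, LHCB2 and RBCS copies 2 of 9 had a summit, against 12 of 12 other photosynthesis genes, a split seen in the data and not tested independently. No expression data were used here, and the biological explanation of recruitment by specific factors was not tested.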
